A study of Triticum aestivum with 18 samples.

How the data were processed

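Gene expression was measured in flag leaves of field-grown wheat (Triticum aestivum) on 18 single-colour Affymetrix wheat arrays, 3 for each of 6 groups. Per the labels' protocols, each array held RNA from the pooled flag leaves of 20 plants of 1 plot, a plot counted as 1 biological replicate, the trial was laid out in 4 randomised complete blocks, and biotin-labelled cRNA was made from 2 µg of total RNA. The groups combined 2 lines of the cultivar Greina, the transgenic line GrKP4 and its null segregant Gr0, with 3 treatments: no inoculation, or seed inoculation with race T1 or race T16 of the common bunt fungus Tilletia caries. Groups and replicate numbers were taken from the sample labels.

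The main table was the authors' deposited table of signal intensities on a linear scale for 61290 probe sets, with 1 column per array. MAS5 is the only tool named in the submitters' processing notes, with no version or settings given in the sources used here. Array medians lay between 20.9 and 22 and array means between 153.9 and 159.3, so no further scaling was applied. The authors also deposited a table of log2 ratios for race T1 against race T16 in each line, each with p-values and false discovery rates; per the file headers, the values behind those tables were normalised with B-Fabric at the Functional Genomics Center Zurich. Each of these tables had 30161 rows. In the table for Gr0, 110 rows carried 55 repeated probe set names and were left out. Another 12 columns of per-array values in these tables matched no sample label and were not used. The direction of the deposited log2 ratios was read from their correlation across probe sets with the fold changes computed here, 0.961 in Gr0 and 0.971 in GrKP4.

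From the intensities, log2(signal + 16) was computed, and every fold change given is on that scale, which understates the change of dim probe sets. A probe set was tested if its signal was at or above its own array's median in at least 3 of the 18 arrays. The 111 AFFX control probe sets were left out of these tests, which left 32821. One linear model with a mean for each group was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), so that the 6 groups shared 1 estimate of the spread. It gave 15 contrasts: each race against no inoculation in each line, race against race in each line, line against line in each treatment, the means of these over lines or treatments, and 3 interactions. P-values were adjusted by the Benjamini-Hochberg method over the probe sets tested, and probe sets with an adjusted p under 0.05 were called. Errors on log2 fold changes are standard errors of the moderated fit, and errors on signals are SDs over arrays. With 3 arrays per group, the number of arrays limits the precision. On simulated data with known changes in 200 of 32821 probe sets, the model recovered 35.8% of changes of 0.5, 82.1% of changes of 1 and 97% of changes of 2 log2 units for Gr0 T1 against T16, and 77.6%, 98.5% and 100% of them for the inoculated against the untreated arrays.

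Gene names came from the array's annotation table, which gave a gene symbol for 1273 probe sets and none for 60017. Of the 1273, 1272 were found by gene identifier in the gene table of assembly IWGSC CS RefSeq v2.1, which was used for names only. Most symbols were LOC numbers. A symbol or synonym other than a LOC number was held by 200 probe sets of 102 genes, and 125 of these probe sets, for 74 genes, were tested. Probe sets whose names end in _s_at or _x_at can bind transcripts of related genes or of the other wheat subgenomes. The genes named were chosen by a rule fixed before the data were examined. It takes, among called probe sets with a gene name, up to 10 with the largest rise and 10 with the largest fall in each mean contrast, and up to 5 and 5 in each contrast of 2 groups, where the arrays compared must not overlap. It adds the 3 largest changes of each gene list, and where nothing was called, the lowest p-values as values only. After the annotation had been read, a gene name was taken to be a symbol or synonym other than a LOC number. Other probe sets given by LOC number or probe set name were chosen after their values were seen.

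Of 19 keyword lists fixed before the data were examined, 4 matched any probe set and 0 had the 5 tested probe sets needed for a test, because the annotation holds symbols and no gene descriptions. Their matches in tested probe sets were 1 for pathogenesis-related proteins, 2 for oxidative stress and 1 for heat shock proteins, and 0 for the cold and dehydration list. In their place, 10 lists of gene symbols were written after the annotation had been read and a few control values had been seen, before any contrast was tested. Of these, 7 had at least 5 tested probe sets and were tested with limma's camera at a preset inter-gene correlation of 0.01. RNA quality and labelling were read from the AFFX probe sets. Exact two-sided permutation tests over all 18564 splits of the 18 arrays into 6 and 12 compared untreated with inoculated arrays (Python 3.11.15, SciPy 1.17.1 for the Benjamini-Hochberg adjustment). Alternatives were pseudocounts of 1 and 64, no filter and a filter at the 75th percentile, quantile normalization, arrays centred on their medians, no intensity trend, array weights, a block for the replicate number, only the arrays compared, and leaving out each array in turn. These were fixed before the data were examined. The removal of 2 arrays together and a block for the untreated arrays alone were added after the data were seen. The latter was added because same-numbered untreated arrays of the lines deviated together from their group means in all 3 pairs (r of 0.272 to 0.58 across the tested probe sets), so that their numbers were taken to pair them. This came from the values, as the labels do not say what a number marks. In no other 2 groups did all 3 pairs have an r over 0.1.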

Results

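The arrays compared flag leaves at Zadoks stages 85 to 87, the dough stages of grain filling, from a field trial in which plants were scored for bunt 16 weeks after sowing. Common bunt is a seed-borne smut disease whose fungus, Tilletia caries, replaces the grain with spores. Inoculated plots were sampled from plants with smut symptoms on their ears, and untreated plots from plants with symptomless ears, so that the comparison of inoculated with untreated groups is one of diseased with healthy plants. GrKP4 carries the gene of KP4, a viral antifungal protein, and Gr0 is the segregant of the same cultivar without it. Each of the 6 groups (Gr0 and GrKP4, each untreated, with race T1 or with race T16) had 3 arrays, 1 per plot.

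RPTR-Ta-X17220-1, one of the array's 64 reporter probe sets, separated the lines in every array. Its signal lay between 317.6 and 1296.5 in the 9 GrKP4 arrays and between 13.6 and 40.3 in the 9 Gr0 arrays, so that the lowest GrKP4 array was 7.88 times the highest Gr0 array. The line labels of all 18 arrays therefore matched this signal. The sources used here do not name the gene behind this probe set, and it is not taken to be KP4.

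**Figure D1:**
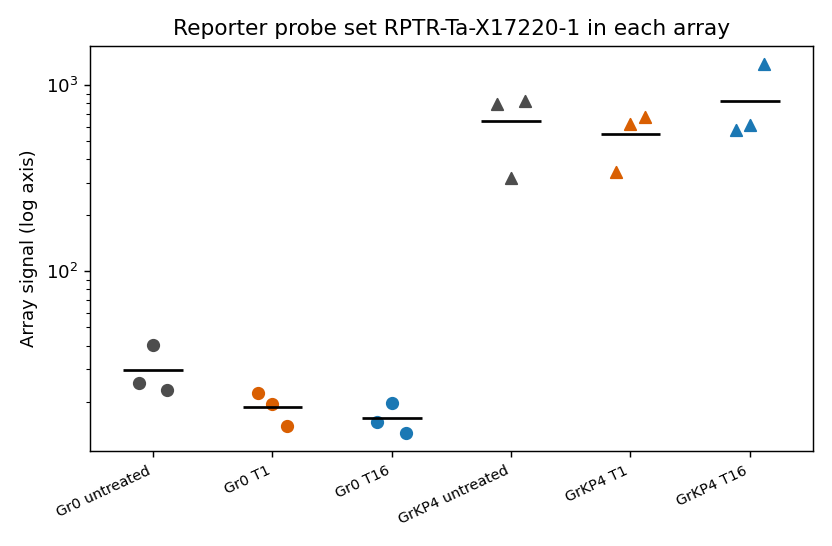
Signal of the reporter probe set RPTR-Ta-X17220-1 (log axis) in each of the 18 arrays by group; points are arrays and lines are means of 3. All 9 GrKP4 arrays lay at 317.6 or above and all 9 Gr0 arrays at 40.3 or below.

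Untreated and inoculated leaves formed separate sets of arrays. The first principal component held 48.1% of the variance, with the 6 untreated arrays between -60.5 and -39.3 and the 12 inoculated arrays between 2.59 and 52.1. The second component held 18% and spread arrays within groups. Gr0 T1 replicate 1 scored -13.5 against 30.4 and 31.9 for the other arrays of its group. GrKP4 T16 replicate 3 scored 29.4 against -31.2 and -11.4. Replicate 2 of both untreated groups lay apart as well, at -38.3 against 8.45 and -4.67 in Gr0 and at -28.4 against 28.9 and 10.4 in GrKP4. Correlations between arrays of log2 values across probe sets were 0.962 to 0.992 within groups and 0.909 to 0.994 between groups.

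**Figure D2:**
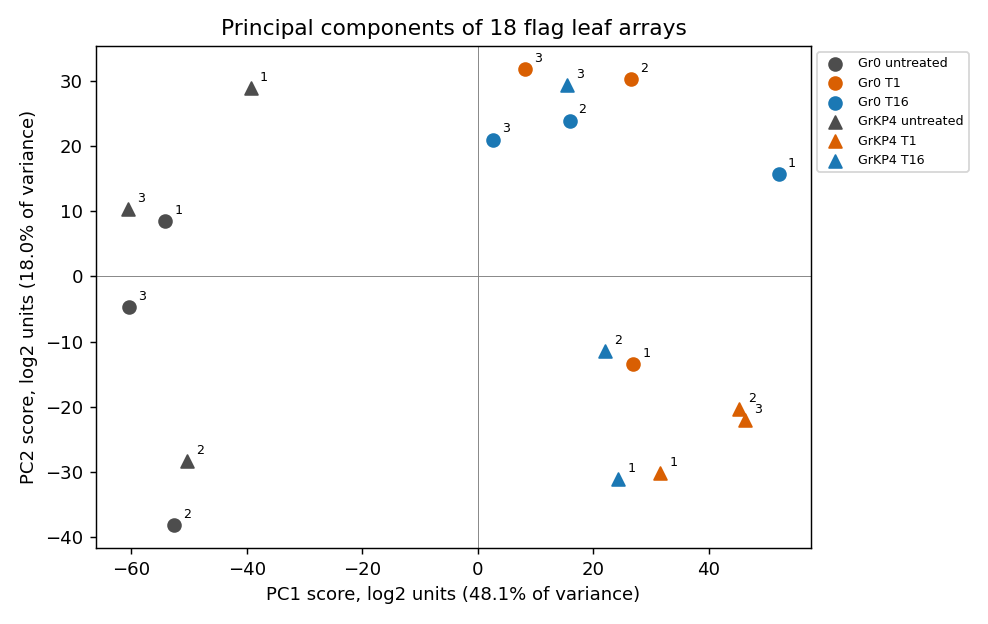
Scores of the 18 arrays on the first and second principal components of log2(signal + 16), with colour for treatment, shape for line and the replicate number beside each point. The 6 untreated arrays lay at -39.3 or below on the first component and the 12 inoculated arrays at 2.59 or above.

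The first question was what changed in the flag leaf of diseased plants, over both lines and both races. PEAMT1, which encodes phosphoethanolamine N-methyltransferase, an enzyme of choline synthesis, fell furthest among genes with a name. Its mean signal was 2341 ± 660.4 (SD, n = 6) in untreated and 157 ± 85.8 (SD, n = 12) in inoculated arrays. WZF1, which encodes a zinc finger protein, rose from 178 ± 172 to 1411 ± 453. The genes of 2 fructan-degrading enzymes changed in opposite directions, with 1-FEH rising from 1076 ± 180.4 to 2238 ± 664 and 6-FEH falling from 84.7 ± 10.9 to 34.5 ± 13.0. In all, 11342 of the 32821 probe sets tested (34.6%) were called in the mean contrast of inoculated against untreated groups, 5383 higher and 5959 lower. Of those changed by at least 1 log2 unit, 915 were higher and 375 lower. The fit treats the untreated arrays as independent, although their values pair them by number across the lines.

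The log2 change of PEAMT1 was -3.89 ± 0.30 (SE; limma, adjusted p = 5.67e-07), and that of WZF1 was 3.18 ± 0.34 (adjusted p = 7.18e-06). For both genes, all 12 inoculated arrays lay beyond all 6 untreated arrays. The other named genes that rose were XIP-I, a xylanase inhibitor (1.09 ± 0.23), 1-FEH (1.00 ± 0.17), Glc1 (0.90 ± 0.25), RPS29, a ribosomal protein (0.76 ± 0.27), hsp16.9A, a small heat shock protein (0.65 ± 0.21), TCTP, translationally controlled tumour protein (0.34 ± 0.05), and the histone gene H2A-9 (0.16 ± 0.06), with 2 of the rbcl probe sets, given below. RPS29 (adjusted p = 0.037) and H2A-9 (adjusted p = 0.0446) were close to the threshold and were not called under several alternatives. The other named genes with the largest falls were RPL9, a ribosomal protein (-1.28 ± 0.13), lgul, glyoxalase I (-1.11 ± 0.12), Prx1 (-1.09 ± 0.09), 6-FEH (-1.04 ± 0.12), rbcl (-0.95 ± 0.20), Gli-8, a gliadin (-0.88 ± 0.25), SAHH, S-adenosylhomocysteine hydrolase (-0.76 ± 0.14), and 2 genes annotated ATI (-0.91 ± 0.22 and -0.68 ± 0.17). Of the 125 tested probe sets with a gene name, 11 were called higher and 44 lower.

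**Figure D3:**
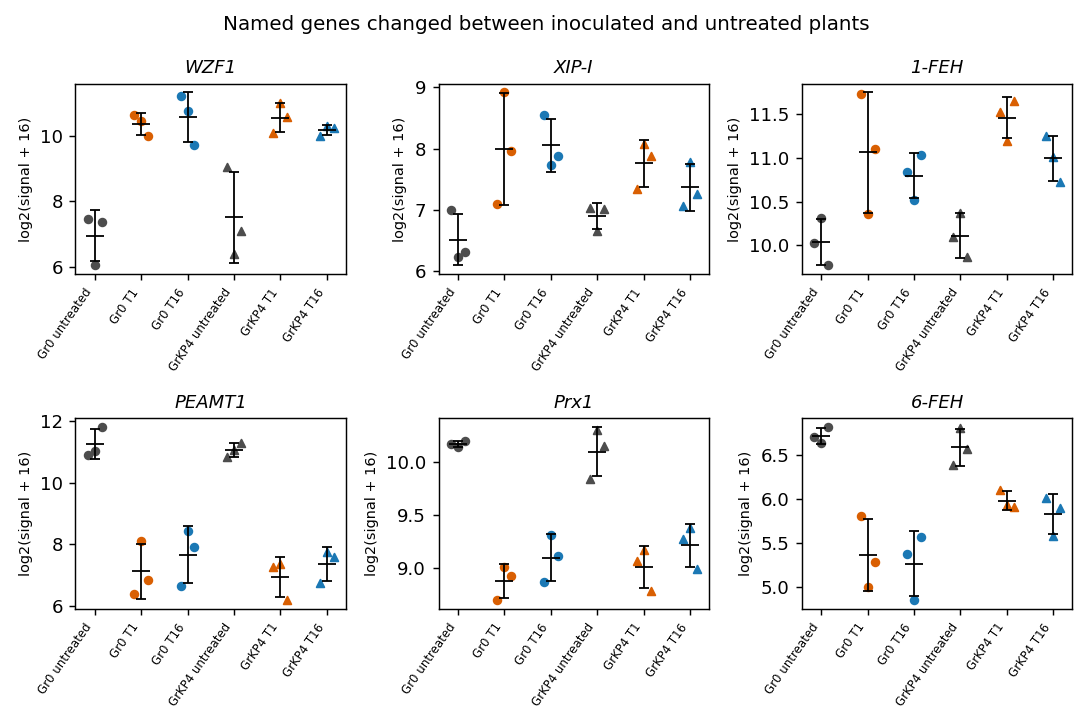
Values of log2(signal + 16) in each array for 3 genes that rose (WZF1, XIP-I, 1-FEH) and 3 that fell (PEAMT1, Prx1, 6-FEH) in inoculated plants; points are arrays, bars are means ± SD of 3. The mean changes over both lines and races were 3.18, 1.09 and 1.00 for the first row and -3.89, -1.09 and -1.04 for the second.

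Large changes were also found among probe sets without a gene name, chosen here by size after their values were seen. Of those given here, 3 rises exceeded that of WZF1, and no fall exceeded that of PEAMT1. TaAffx.21593.1.S1_at rose by 4.86 ± 0.27 log2 units and Ta.15207.1.S1_at by 4.40 ± 0.46. TaAffx.70216.1.S1_s_at and Ta.21419.1.S1_x_at fell, with log2 changes of -3.28 ± 0.27 and -3.27 ± 0.41. Among genes known only by a LOC number, LOC543123 rose by 3.52 ± 0.28 and LOC542847 by 2.77 ± 0.32, and LOC780599 and LOC543363 had changes of -2.87 ± 0.22 and -2.40 ± 0.25.

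Genes of sugar, starch and fructan metabolism were mostly lower in inoculated plants. Of 12 tested probe sets, which stand for 7 genes, 9 fell (5 genes), 1 rose and 2 were not called. The list was shifted downward against all other probe sets (camera, adjusted p = 0.00476, and 0.154 with an estimated correlation). Probe sets of 1 gene count as separate members in both. Those that fell included 6-FEH, GAPN, the non-phosphorylating glyceraldehyde-3-phosphate dehydrogenase (-0.52 ± 0.13), TSA (-0.45 ± 0.07) and AGA.1 (-0.40 ± 0.06), and the one that rose was 1-FEH. Adjusted over the list alone, 10 were lower and 1 higher.

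Of 20 probe sets of photosynthesis and Calvin cycle genes, which stand for 8 genes, 11 fell (6 genes), 2 rose (1 gene) and 7 were not called. The list was shifted downward (camera, adjusted p = 0.0309, and 0.336 with an estimated correlation). Adjusted over the list alone, 12 were lower and 2 higher. Pgk-1, phosphoglycerate kinase, had a change of -0.40 ± 0.07, PsbP and PsbO of the oxygen-evolving complex had -0.23 ± 0.08 and -0.15 ± 0.04, and the thioredoxin gene Trx-M had -0.15 ± 0.05. PsbP and Trx-M were not called in 14 and 6 of 28 alternatives, quantile normalization and no filter among them. The probe sets for rbcl, the large subunit of Rubisco, disagreed. The largest change was -0.95 ± 0.20 at a mean untreated signal of 175, whereas the probe set with the brightest signal, 24322 ± 602 in untreated arrays, rose by 0.09 ± 0.03, and after quantile normalization its change was 0 because it ranked highest on every array. This rise was not called in 6 of 28 alternatives, and that of the other rbcl probe set that rose (0.17 ± 0.06) in 3 of 27.

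In the methyl transfer list, 3 of 5 probe sets fell and 2 were not called (camera downward, adjusted p = 0.0493; adjusted p = 0.336 with an estimated correlation, and 0.0641 after quantile normalization). The 3 were PEAMT1 and both probe sets of SAHH. Adjusted over the list alone, the count was also 3. The defence and oxidative stress list had 3 probe sets higher, 7 lower and 12 not called of 22, and was not shifted as a whole (camera, adjusted p = 0.18). XIP-I and Glc1 rose in it, while lgul, Prx1 and the glutathione S-transferase gene GSTZ1 fell. The change of GSTZ1 (-0.25 ± 0.08) was not called in 3 of 18 refits without 1 array, and its estimate rested on GrKP4. In that line it was -0.51 under T1 and -0.54 under T16, calls lost in 2 and 3 of 6 such refits. Its interactions of line with race T1 and with race T16, -0.62 and -0.49, were of similar size but were not called. Cytoskeleton and chromatin genes (2 higher, 2 lower and 20 not called of 24; adjusted p = 0.349) and translation genes (2 higher, 2 lower and 7 not called of 11; adjusted p = 0.855) were not shifted either. In the chromatin list WZF1, a zinc finger protein, and H2A-9 rose and the 2 probe sets of the histone gene wcH2B-6 fell (-0.41 ± 0.10 and -0.22 ± 0.07, the second not called in 4 of 28 alternatives). The lists of cold, dehydration and heat stress (hsp16.9A higher, 3 not called), gibberellin synthesis (2 not called) and anther genes (raftin1b, -0.07 ± 0.04, not called) had too few members for the list test.

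Transcripts of grain storage proteins and seed inhibitors were included as markers of another tissue. Of 10 tested probe sets, 5 fell and 5 were not called (camera downward, adjusted p = 0.0151; adjusted p = 0.336 with an estimated correlation), and adjusted over the list alone 7 were lower. For Gli-8 the difference came from some of the untreated arrays. Its signal was 274.3 in GrKP4 untreated replicate 1, 116.5 in GrKP4 untreated replicate 3, 58.4 in Gr0 untreated replicate 1 and 48.9 in Gr0 untreated replicate 2. In the 2 remaining untreated arrays it was 31.4 and 32.4, within the range of 23.5 to 41.1 of the 12 inoculated arrays. GluD3-4, also called, did not follow this, with 121.9 in GrKP4 untreated replicate 1, 110 to 145 over the untreated arrays and 95.3 to 127.5 over the inoculated ones, and its call (-0.15 ± 0.06) was lost in 16 of 18 refits without 1 array. All 3 called ATI probe sets were highest in GrKP4 untreated replicate 1, at 156.7 for LOC543281 and at 83.6 and 104.3 for the 2 of LOC543286, the second being Ta.58.1.S1_at. In Ta.58.1.S1_at all 6 untreated arrays, 29.3 to 104.3, lay above all 12 inoculated arrays, 23.7 to 29. Without GrKP4 untreated replicate 1 the changes were -0.57 ± 0.17 for Gli-8, -0.44 ± 0.10 for the first LOC543286 probe set and -0.30 ± 0.05 for Ta.58.1.S1_at, all still called.

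Control probe sets also differed between untreated and inoculated arrays. The mean log2 signal of the poly-A spikes, which are added to the RNA before labelling, was 8.66 ± 0.23 (SD, n = 6) in untreated and 8.25 ± 0.20 (SD, n = 12) in inoculated arrays (exact permutation test, p = 0.00151, adjusted p = 0.00452 over 6 measures). The log2 ratio of 3' over 5' signal of the dap spike was 1.40 ± 0.08 in untreated and 1.64 ± 0.12 in inoculated arrays (exact p = 0.000485, adjusted 0.00291). The same ratio for wheat ubiquitin was -1.24 ± 0.09 and -1.37 ± 0.11 (exact p = 0.0316, adjusted 0.0631), and those for sucrose synthase and glucose-6-phosphate dehydrogenase had adjusted p of 0.418 and 0.658.

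Each race was next compared with no inoculation within each line. In Gr0, 5233 probe sets were called under race T1, 2766 higher and 2467 lower, and 4554 under race T16, 2283 higher and 2271 lower. In GrKP4, 7388 were called under T1, 3534 higher and 3854 lower, and 3738 under T16, 1865 higher and 1873 lower. PEAMT1 fell in all 4 comparisons, with log2 changes of -4.13 (Gr0 T1), -3.58 (Gr0 T16), -4.13 (GrKP4 T1) and -3.70 (GrKP4 T16), each ± 0.49. WZF1 rose in all 4, by 3.40, 3.60, 3.04 and 2.67, each ± 0.55.

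RPL9 also fell in all 4 comparisons (-1.24, -1.25, -1.23 and -1.41, each ± 0.22), as did lgul (-1.01, -1.19, -1.09 and -1.17, each ± 0.19). In Gr0, 6-FEH and Prx1 were among the largest falls under both races, with -1.35 and -1.45 (each ± 0.20) for 6-FEH and -1.30 and -1.08 (each ± 0.15) for Prx1, given for 1 probe set throughout. XIP-I rose in Gr0 by 1.48 ± 0.37 under T1 and 1.54 ± 0.37 under T16 in the same probe set, and TCTP by 0.47 and 0.33 (each ± 0.08). Under T1, 1-FEH also rose in Gr0, by 1.03 ± 0.27, a call lost in 2 of 6 refits without 1 array compared. In GrKP4, 6-FEH was called lower too (-0.60 under T1 and -0.75 under T16 in the same probe set), calls lost in 5 and 3 of 6 such refits. A gene given here for 1 line thus need not be particular to it, as 6-FEH was not. In GrKP4 under T1, hsp16.9A rose by 1.63 ± 0.34, 1-FEH by 1.35 ± 0.27, Glc1 by 1.22 ± 0.41 and the tubulin gene Tubb5 by 0.65 ± 0.15, while the ATI gene LOC543281 (-1.35 ± 0.36) and Prx1 (-1.09 ± 0.15) fell. In GrKP4 under T16, 1-FEH rose by 0.88 ± 0.27, TCTP by 0.36 ± 0.08 and H2A-9 by 0.31 ± 0.09, while rbcl (-1.34 ± 0.32) and the ATI gene LOC543286 (-0.92 ± 0.28) fell. Both ATI values rested on GrKP4 untreated replicate 1, without which they were -0.79 ± 0.25 (adjusted p = 0.0477) for LOC543281 under T1 and -0.44 ± 0.16 (adjusted p = 0.113, not called) for LOC543286 under T16. Of the refits without 1 of the 6 arrays compared, the call was lost in 6 for Glc1 under T1 and in 5 for 1-FEH, 6 for H2A-9, 5 for LOC543286, 3 for rbcl and 1 for TCTP under T16. It was lost in 1 for LOC543281 under T1 (without GrKP4 T1 replicate 3, -1.31, adjusted p = 0.0533), and for XIP-I in Gr0 in 3 under T1 and 2 under T16. The counts depended on single arrays. Without GrKP4 untreated replicate 3, T1 called 4093 and T16 called 1190 probe sets in GrKP4, T1 called 4245 without its replicate 3, T16 called 2021 and 2005 without its replicates 1 and 2, and in Gr0 T16 called 2050 without its replicate 1.

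**Figure D4:**
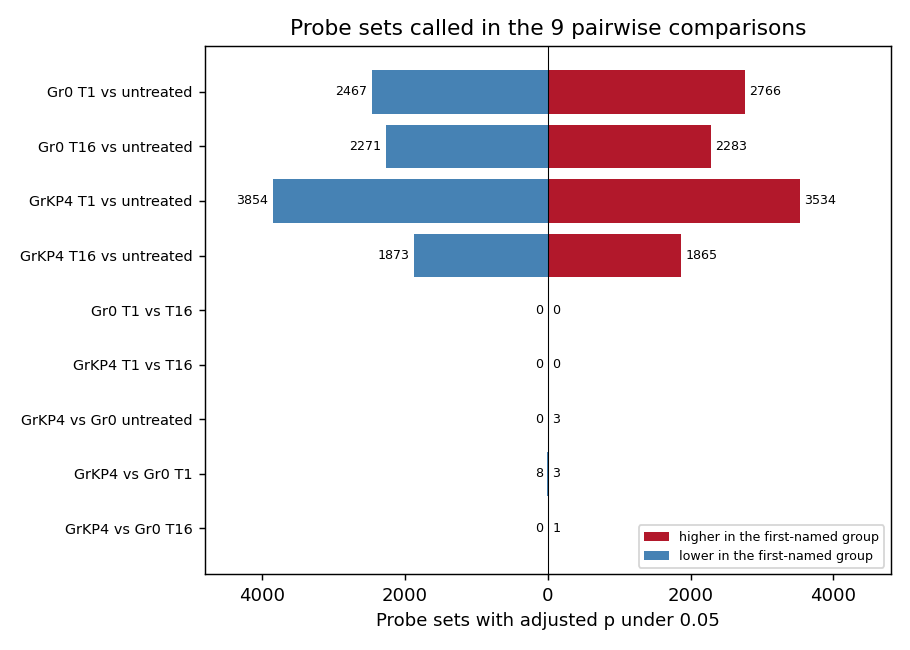
Number of probe sets with an adjusted p under 0.05 in each of the 9 comparisons of 2 groups, with those higher in the first-named group to the right and those lower to the left. Inoculated against untreated plants gave 3738 to 7388 calls, and race against race or line against line gave 0 to 11.

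The 4 changes were alike across lines, where the comparisons share no arrays. Across the tested probe sets, which are not independent replicates, the log2 changes under T1 in Gr0 and in GrKP4 had a Pearson correlation of 0.742 and those under T16 of 0.800, with a value near 0 in 20 simulations of unchanged, unrelated groups. Same-numbered untreated arrays of the lines deviated together, and 20 simulations with noise shared in these pairs (r = 0.439), added after the data were seen, gave 0.223 under each race. The covariances were 0.1861 under T1 and 0.1599 under T16, against 0.0073 and 0.0072 in those simulations. All simulations of unchanged groups drew noise separately for each probe set. In the real arrays deviations were shared across probe sets, with r from -0.44 to 0.58 between same-numbered arrays. A correlation arising by chance can thus lie further from the simulated values than these simulations show. Under T1, 1669 probe sets were called higher in both lines, against 298 for independent lists of those sizes, and 1418 lower in both, against 290. Under T16, 1103 were higher in both against 130 and 1155 lower in both against 130, where independence leaves the pairing out. Within a line, T1 and T16 are compared with the same untreated arrays, which alone gives a correlation of 0.501 in Gr0 and 0.502 in GrKP4 in the simulations. The observed values were 0.925 and 0.898, with covariances of 0.2087 and 0.1993 against simulated covariances of 0.0162 and 0.0163. The untreated groups of 3 are too small to be split, so part of the excess may be due to the shared controls. In all 4 comparisons, 933 probe sets were called higher and 896 lower.

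The races were then compared with each other. In neither line was any probe set called between T1 and T16. By limma, 1289 probe sets in Gr0 and 2728 in GrKP4 had an unadjusted p under 0.05, and the smallest adjusted p was 0.999 and 0.184. In the authors' deposited table for Gr0, 0 probe sets had a false discovery rate under 0.05, with 1156 at an unadjusted p under 0.05. In the authors' deposited table for GrKP4, 2 did, TaAffx.101303.1.S1_at (log2 ratio 0.5931) and Ta.7999.2.S1_a_at (0.4394), both without a gene name, with 2681 at an unadjusted p under 0.05. Computed here, their changes were 0.495 and 0.396 with limma adjusted p of 0.566 and 0.6.

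Named genes with the lowest p between the races did not pass the threshold. In GrKP4 they were PRK, phosphoribulokinase (-0.18 ± 0.06), hsp16.9A (1.06 ± 0.34) and PR5, a thaumatin-like pathogenesis-related protein (0.77 ± 0.27), with limma adjusted p of 0.516, 0.516 and 0.53. In Gr0 they were AGA.1 (-0.20 ± 0.08), RPS29 (-0.79 ± 0.44) and TCTP (0.14 ± 0.08), each with an adjusted p of 0.999. Over both lines, 2 probe sets were called, both lower under T1 and both for the transcript Ta.975.2, which has no gene name here. Ta.975.2.S1_at had mean signals of 647 ± 153 (Gr0 T1), 1143 ± 59.6 (Gr0 T16), 641 ± 70.6 (GrKP4 T1) and 1332 ± 202 (GrKP4 T16), and a log2 change of -0.93 ± 0.12 (adjusted p = 0.0306). Leaving out any single array of the 4 inoculated groups except Gr0 T1 replicate 3 or GrKP4 T1 replicate 3 left 0 called. The named genes with the lowest p, AGA.1 (-0.17 ± 0.06), GAPN (-0.42 ± 0.14) and PR5 (0.52 ± 0.19), had an adjusted p of 0.739, and none of the 7 lists tested was shifted between the races (smallest camera adjusted p = 0.476).

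The lines were compared to see what the transgene changed in the leaf. The reporter probe set was called in each treatment, higher in GrKP4 by 3.77 ± 0.35 log2 units in untreated plants (limma, adjusted p = 0.000582), 3.96 ± 0.35 under T1 (adjusted p = 0.000292) and 4.61 ± 0.35 under T16 (adjusted p = 3.55e-05). Apart from it, few probe sets were called, and no gene with a readable name was. Few calls do not show that few probe sets differed. On simulated data for the lines under T1, only 41.8% of changes of 0.5 log2 units were recovered. For changes of 1 and 2 log2 units it was 89.6% and 100%, so mainly smaller differences would be missed there. Ta.8854.1.A1_at and TaAffx.128827.3.A1_at, which have no gene name, were higher in untreated GrKP4 by 1.49 ± 0.19 and 1.58 ± 0.21. Under T1, 11 probe sets were called, 3 higher and 8 lower, and under T16 only the reporter was. With array weights far more were called under both races, as given under the processing alternatives below.

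Among the 11 called under T1 were LOC542837 (higher by 0.81 ± 0.11), LOC543328 (-1.30 ± 0.20), Ta.23032.1.S1_at (-1.53 ± 0.23) and Ta.21069.2.S1_a_at (-1.39 ± 0.22), chosen here after their values were seen. By limma, an unadjusted p under 0.05 was found for 671 probe sets in untreated plants, 6222 under T1 and 2501 under T16. Without Gr0 T1 replicate 1, 656 probe sets were called between the lines under T1, and without each of the other arrays of these groups in turn the count lay between 2 and 9. Leaving out 1 untreated array left 1 called in 5 of 6 cases. The named genes with the lowest p did not pass the threshold. Under T1 they were hsp16.9A (1.51 ± 0.34, limma adjusted p = 0.0758), UBC1, a ubiquitin-conjugating enzyme (-0.39 ± 0.10, 0.0856), and cys1 (-0.34 ± 0.08, 0.0862). Under T16 they were the 2 probe sets of cys1 (-0.29 ± 0.08 and -0.31 ± 0.09, adjusted p = 0.51 each) and another probe set of H2A-9 (0.89 ± 0.27, 0.538). In untreated plants they were wci (0.27 ± 0.10), Gli-8 (1.01 ± 0.41) and ALP (0.62 ± 0.29), each with an adjusted p of 1.

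Over the 3 treatments together, 21 probe sets were called between the lines, 10 higher and 11 lower in GrKP4. The reporter had a log2 difference of 4.11 ± 0.20 (adjusted p = 6.63e-08), with mean signals of 673 ± 291 (SD, n = 9) in GrKP4 and 21.5 ± 8.06 (SD, n = 9) in Gr0. After it came Ta.8854.1.A1_at (1.19 ± 0.11) and Ta.21783.1.S1_at (1.16 ± 0.13) among those higher, and Ta.20421.1.S1_at (-1.16 ± 0.18) and Ta.23032.1.S1_at (-0.89 ± 0.13) among those lower. LOC542837 was higher by 0.54 ± 0.06 and LOC100037560 lower (-0.63 ± 0.11). The named genes with the lowest p were the 2 probe sets of cys1 (-0.23 ± 0.05 each, adjusted p = 0.138 and 0.15) and another probe set of 6-FEH (0.35 ± 0.09, adjusted p = 0.154), which were not called. The sugar, starch and fructan list was shifted upward in GrKP4 (camera, adjusted p = 0.0111; adjusted p = 0.217 with an estimated correlation), although 0 of its 12 probe sets were called over all probe sets and 2 when adjusted over the list alone. None of the other 6 lists tested was shifted (smallest adjusted p = 0.134). The count of 21 rose to 110 without GrKP4 T16 replicate 3 and to 109 without Gr0 untreated replicate 2, and fell to 8 without any one of Gr0 untreated replicate 3, GrKP4 untreated replicate 2 or Gr0 T1 replicate 2.

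Whether the change from healthy to diseased plants differed between the lines was tested by the interactions. Inoculated plants of both lines were chosen for smut symptoms, so a difference in infection between the lines lies outside this comparison. Recovery of simulated changes was not computed for the interactions, so an absence of calls does not show equal responses. No probe set was called for the difference between lines in the change under T1, in the change under T16, or in the difference between races. By limma, unadjusted p-values under 0.05 numbered 3943, 1501 and 1778, and the smallest adjusted p-values were 0.379, 0.83 and 0.723. The named genes with the lowest p were GSTZ1 (-0.55 ± 0.16 and -0.62 ± 0.18 in its 2 probe sets) and CAT1, catalase (0.46 ± 0.13) for T1, GSTZ1 (-0.44 ± 0.16 and -0.49 ± 0.18) and GA20ox1d, a gibberellin 20-oxidase (0.34 ± 0.13) for T16, and hsp16.9A (1.35 ± 0.48), Eif4B (-0.46 ± 0.17) and PRK (-0.21 ± 0.08) for the races, with adjusted p of 0.379, 0.864 and 0.891.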

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

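The tests of RNA quality in the 2 arrays and of their reporter signal below, the comparisons of splits by same-numbered pairs and by unadjusted p, the comparison of errors with and without a measure in the model, the use of the grain changes without 1 array, and the reading of counts of 0 were chosen after the results were seen. The tests of the 2 RNA and labelling measures, of grain RNA and of the splits were written before their own results, when the group differences in those measures were already known. The control probe sets were outside the main comparisons, and 2 of the 20 wheat control probe sets with sufficient signal were higher in inoculated than in untreated arrays after Benjamini-Hochberg adjustment over the 20. The 18S rRNA probe set was higher by 0.38 on the log2 scale, 7.01 against 6.62 (exact permutation test, p = 0.0137, adjusted p = 0.0456), with 6 of 12 inoculated arrays above all untreated ones. The 5' actin probe set was higher by 0.19, 5.77 against 5.58 (exact permutation p = 0.00382, adjusted p = 0.0255), while the middle probe set of the same gene was not higher (-0.12, adjusted p = 0.143).

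The largest pattern was the difference of 11342 probe sets between inoculated and untreated arrays. In 100 splits of the arrays within lines, the real one included, only the real split gave as many calls, and the next highest gave 5423. In 100 splits drawn only from those that, like the real one, part no same-numbered untreated arrays, again only the real one did, with a highest other of 2548. Chance alone is thus an unlikely source of this count. A difference in RNA integrity or in labelling stays open as a cause. The change expected from the slope on the ubiquitin 3' over 5' ratio within groups had r = 0.559 with the observed change over the called probe sets (0.406 to 0.678 without 1 array) and accounted for 11% of it. With that ratio in the model 5964 probe sets were called, while the median absolute change over the 11342 went from 0.39 to 0.37 and its median SE from 0.09 to 0.11. For the poly-A spike level, r was 0.339 (-0.359 to 0.557), the share 6.6% and the count 3353, with a median absolute change of 0.35 and a median SE of 0.14. The changes thus kept most of their size and calls were lost mainly to wider errors. This does not decide between a part and the whole, since a noisy measure gives too small a slope within groups. The dap spike ratio, which also differed (exact permutation test, adjusted p = 0.00291), was not put in the model. Such causes cannot be told apart from the treatment, since the spike level differed with it (same test, adjusted p = 0.00452). The ubiquitin ratio, whose own difference did not pass the threshold (same test, adjusted p = 0.0631), is a noisy stand-in for RNA integrity.

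Grain storage transcripts formed a second pattern, with 4 of 5 called probe sets (Gli-8 and 3 of ATI genes, but not GluD3-4) highest in GrKP4 untreated replicate 1. Traces of grain RNA in single untreated samples may be a part of the source, but not in this array alone, since without it the changes of Gli-8 (-0.57 ± 0.17) and Ta.58.1.S1_at (-0.30 ± 0.05) were still called, and all 6 untreated arrays of Ta.58.1.S1_at (29.3 to 104.3) lay above the inoculated range (23.7 to 29). Of the 28 other list members, 5 tested and not called and 23 too dim to be tested, 20 had their highest untreated signal in that array, where chance gives 4.7 (4 of the 5 and the rest among the dim ones), but members of 1 gene family are not independent. Expression of these genes in the leaf itself was not tested and stays open, as does a smaller trace from diseased ears, which hold spores in place of grain.

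The third pattern was the place of Gr0 T1 replicate 1 and GrKP4 T16 replicate 3, which lay apart from their groups on the second principal component. Replicate 2 of both untreated groups lay about as far from its group, and the tests here did not cover these arrays. An exchange of line labels is excluded by the reporter, since these arrays lay at least 14.3 times from the nearest array of the other line. Poorer technical quality of these arrays cannot be told apart from other causes. Of 12 quality values, 2 lay outside the range of the other 16 arrays, where chance gives 1.4, and both were lower 3' over 5' ratios, the side opposite to degradation. As first written, this test took any value outside the range as a fit, by which the 2 values would have fitted poorer quality, and the poorer side was required only after that result was seen. No biological explanation was tested, as the labels give no plot or severity for single arrays.

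Other splits of the same arrays bear on the remaining counts. For each comparison of 3 against 3 arrays only 10 splits exist, too few for a share under 0.05. The inoculated against untreated counts of 5233, 4554, 7388 and 3738 (Gr0 T1, Gr0 T16, GrKP4 T1, GrKP4 T16) were reached by 1 split each, the real one, with highest other counts of 0, 0, 0 and 1419. For T1 against T16 the real count was 0 in both lines, which any split reaches (10 of 10), so the count of calls decides nothing. The highest other was 374 in Gr0 and 0 in GrKP4, and the split with 374 put replicates 2 of both races on one side and replicates 3 on the other. By an unadjusted p under 0.05 (limma), 4 other splits exceeded the real 1289 in Gr0, with up to 4375. In GrKP4, 0 exceeded the real 2728, with a highest other of 1970. Between the lines, the real counts of 3 (untreated), 11 (T1) and 1 (T16) were reached by 3, 1 and 2 splits, with highest other counts of 24, 2 and 1. The split with 24 put both untreated replicates 2 on one side, and of the splits that part all 3 same-numbered pairs, the real one gave 3 and the others at most 1. By an unadjusted p under 0.05 (limma), the real line counts were 671, 6222 and 2501. They were exceeded by 9, 0 and 1 other splits, with highest others of 4927, 3177 and 4298. Over all treatments, the line count of 21 was reached by 1 of 100 splits, the real one, with a highest other of 8. That share is under 0.05, but the real count itself fell to 8 without single arrays. The 4374 probe sets with an unadjusted p under 0.05 were exceeded by 9 other splits, with up to 6919, so chance is not excluded for them. Of the 47 splits that part all 3 untreated pairs as the real one does, the others gave at most 1 call, and 2 exceeded 4374, with up to 5420. The race count of 2 was reached by 14 of 100, with a highest other of 411, so chance is not excluded. The interaction counts of 0 are likewise reached by any split (100 of 100), so these splits decide nothing about them, although this test as first written took such a share as a fit with chance. Their highest others were 12, 2262 and 7 for T1, T16 and the races. By an unadjusted p under 0.05 (limma), the real 3943, 1501 and 1778 were exceeded by 3, 44 and 27 other splits of these 100, which were not restricted by untreated pairs. The splits with 24 calls against 3 and 411 against 2 point to a structure of the samples, but whether such counts exceed what the highest of many splits gives by chance was not tested.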

How the results depend on the processing

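The removal of 2 arrays together and the block for untreated arrays alone were chosen after the data were seen. Of the alternative counts, 233 stayed within 1.5 times the main count and 69 did not. The 233 include counts of 0 that stayed at 0, as in every refit without 1 array for contrasts with no calls. They thus overstate how stable the contrasts with calls were. Of the 18 genes ranked in the inoculated against untreated contrast, 16 kept their direction and their call under every alternative that gave a value for them. RPS29 and H2A-9 were the exceptions (not called in 10 and 18). The size was less stable, and 7 of the 18 moved by over 1.5 times. With pseudocounts of 1 and 64, hsp16.9A was 1.26 and 0.28, H2A-9 0.29 and 0.06 and ATI LOC543286 -1.17 and -0.31. With 64, RPS29 was 0.46, 6-FEH -0.60, ATI LOC543281 -0.49 and Gli-8 -0.56. Gli-8 (-0.57) and LOC543286 (-0.44) moved so also without GrKP4 untreated replicate 1. That contrast's count ranged from 9393 to 11529 without single arrays. No scaling moved the share of higher calls by over 10 percentage points in contrasts with over 13 calls, and in GrKP4 against Gr0 under T1 it moved from 27.3% of 11 to 38.5% of 13 with centred arrays.

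With array weights, GrKP4 T1 and T16 against untreated called 13006 and 13346, GrKP4 T1 against T16 called 833, GrKP4 against Gr0 called 2926 under T1, 3469 under T16 and 2467 over treatments, and the line by T16 interaction 6. The weights were uneven, at 5.79 for GrKP4 T16 replicate 2 against 0.95 and 0.41 in its group. GrKP4 untreated replicate 3 had 2.49 against 0.58 and 0.5. These groups thus leaned on single arrays, and how far that raised the counts was not tested. With only the arrays compared, where fewer arrays set the spread, Gr0 T1 and T16 against untreated called 3473 and 2972, GrKP4 T16 called 2103, the lines called 0 untreated and 1 under T1, and the races over both lines 0. The stricter filter, with 17403 probe sets tested, called 10 between the lines over treatments, and quantile normalization called 1 between the races. The authors' deposited table for GrKP4 T1 against T16 had 2 against 0 here. With an estimated correlation, 0 lists against 4 were shifted between inoculated and untreated arrays. Without both Gr0 T1 replicate 1 and GrKP4 T16 replicate 3, GrKP4 against Gr0 called 2166 under T1, 2 under T16 and 1603 over treatments, the line by T1 interaction 410 and the races 0; these arrays were picked because they lay apart from their groups, which lowers the spread by selection.

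The replicate number as a block moved the counts of GrKP4 T1 against T16 from 0 to 4, of the races over both lines from 2 to 4 and of the lines under T1 from 11 to 24, and ended no other 0. With the block for the untreated arrays alone, which their values pair, the lines stayed at 3 calls untreated. This block was not applied to the inoculated against untreated contrasts, and the exact permutation tests also leave the pairing out. Over all groups the values do not settle whether the numbers pair the samples, and no test set them against chance. Of 45 pairs of same-numbered arrays, 22 had deviations from the group means with r over 0.1 (range -0.44 to 0.58), and 11 of 18 arrays correlated best with one of their own number.

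Without single arrays, where a group of 2 is assumed to vary like the others, the counts ranged as follows. For T16 against untreated they were 2050 to 4558 in Gr0 and 1190 (without GrKP4 untreated replicate 3) to 4114 in GrKP4, and for T1 3660 to 4407 in Gr0 and 4093 to 8119 in GrKP4. Between the lines they were 1 to 3 untreated, 2 to 656 under T1 (656 without Gr0 T1 replicate 1), 1 to 3 under T16 and 8 to 110 over treatments (110 without GrKP4 T16 replicate 3). Between the races over both lines they were 0 to 2. They stayed at 0 for T1 against T16 within each line and for the 3 interactions. The folds of dim probe sets are limited, since array medians lay near 21 and a pseudocount of 16 was added.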

Other observations

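Some wheat control genes outside the tested set fell in diseased plants. All 3 probe sets of glucose-6-phosphate dehydrogenase, an enzyme of the pentose phosphate pathway, were lower in inoculated arrays, with log2 differences of -0.32 (3' probe set), -0.44 (middle) and -0.32 (5'), and exact permutation adjusted p of 0.0221, 0.00862 and 0.0339 over 20 probe sets. The difference was close in both lines, -0.42 in Gr0 and -0.46 in GrKP4 for the middle probe set. The 3' ubiquitin probe set was lower by a log2 difference of -0.20 (adjusted p = 0.0456), and the middle and 5' probe sets were not past the threshold (-0.13 and -0.07). The middle probe set of sucrose synthase, which splits sucrose in sink and transport tissue, differed by 0.78 in Gr0 and 0.11 in GrKP4. It did not pass over both lines (0.44, adjusted p = 0.106), and the difference between lines was not tested.

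Probe sets that differed between the lines also changed with the disease in some cases. Ta.20421.1.S1_at, lower in GrKP4 by a log2 difference of -1.16 ± 0.18, was higher in inoculated than in untreated plants by 3.01 ± 0.19 (limma, adjusted p = 1.55e-07), with mean signals of 28.3 in the 6 untreated and 401 in the 12 inoculated arrays. LOC542837, higher in GrKP4, was lower in inoculated plants (-0.89 ± 0.07). These were chosen after their values were seen.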
